A study of Homo sapiens with 9 samples.

How the data were processed

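RNA sequencing of MDA-MB-231 cells gave 9 libraries in 3 groups of 3, named by the labels as treated for 16 h with DMSO, I-BRD9 or ipatasertib. Per the labels' protocols, messenger RNA was captured on poly-T beads and fragmented, the first strand was primed with random hexamers, and the second strand was made with dTTP, so strand is not marked in these libraries and reads of overlapping antisense genes cannot be told apart. The submitters' processing notes name HISAT2, Bowtie2 and the genome build GRCh38.p13, without versions or roles. The quantification tool, the gene annotation and any gene filter are not given in the sources used here.

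The authors deposited 1 table of FPKM (fragments per length of transcript, scaled to the mapped fragments of the library), per the file headers, with 2 decimals, for 17219 genes named by NCBI gene ID and symbol. All 9 of its sample columns were used and matched to libraries by name. No scaling between libraries is stated, and the totals of 569606 to 625265 FPKM per library show that they were not set to a common sum. No 2 libraries held identical values. FPKM is a share of each library, so a gene that takes more of it lowers all others, and the total RNA per cell is not measured.

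Absolute depth is unknown. In 13 of 14 low histone genes examined, values fell on whole multiples of 1 read (93 of 97 values above 0, 95.9%, within 0.0065 FPKM), which gave depths of 0.962 to 1.037 relative to each other, with an error of at most 0.62% in simulated data. No count test was run, since the value of 1 read depends on each gene's length. Precision therefore rests on the spread between libraries. The median standard error of a log2 fold change was 0.052 in each comparison with DMSO.

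Each value was taken as log2(FPKM + 1). Genes with a mean of at least 1 FPKM over the 9 libraries were tested, 11483 in all, and 5736 were left out. Linear models with 1 mean per group were fitted to all 9 libraries with limma 3.58.1 in R 4.3.3, with 6 residual degrees of freedom and a variance trend (7.45 prior degrees of freedom), and p was adjusted by the method of Benjamini and Hochberg with a threshold of 0.05. Fold changes on the log2 scale understate the change of low genes because of the pseudocount of 1, and folds given in the text are ratios of mean FPKM. The comparisons were I-BRD9 against DMSO, ipatasertib against DMSO and I-BRD9 against ipatasertib. No covariate was used. Tests are two-sided.

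Before the data were examined, 37 gene lists were fixed. They cover FOXO, ATF4, YAP and p53 targets, the PI3K-AKT-mTOR pathway, cholesterol, fatty acid and energy metabolism, hypoxia, chaperones, the cell cycle, ribosome biogenesis, interferon, NF-kB, MAPK and MHC class I genes, matrix, mesenchymal, epithelial and Polycomb-related genes, SWI/SNF and BET proteins, arginine methyltransferases, autophagy, the BCL2 family, RNA quality and other cell types. The 33 with at least 3 tested genes were compared with all other tested genes by camera with a preset correlation of 0.01, and again with a correlation estimated from the data, under which 0 lists passed in any comparison. The list-wise rotation test fry, which asks whether a list's genes move one way on balance, was an alternative. All members were matched by symbol. Of the listed genes, 13 mitochondrially encoded genes, 11 histones, TWIST1, TWIST2, KRT5, PAX6, SOX17, TBX5, HAND2, HOXA5, HOXA9, CLEC1A, MS4A1 and HBB, among others, were not analysed here.

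The genes named in the text follow a rule fixed at the same time. It takes genes of the route in the series title (among them BRD9, BRD7, AKT1, AKT2, EZH2, EED, SUZ12 and PRMT5), the 10 highest and 10 lowest fold changes per comparison with DMSO among genes whose libraries do not overlap, up to 4 members with the smallest adjusted p of each list that passed or held at least 3 changed genes, the 10 genes per direction with the largest shared change and 5 per direction with opposite changes, and the 5 highest and 5 lowest of the direct contrast. Genes named outside this rule, chosen after their values were seen, are MT2A, H1-4, H3C3, CD14, CD68, COL1A1, DUSP6 and those in the opening 2 paragraphs of the closing section. Some genes that the rule takes are not reported here. Coordinates are those of the GENCODE annotation of GRCh38.

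The model was tested on simulated data with the means and spreads of the real genes, in 5 runs with 200 changed genes each. For I-BRD9 against DMSO it recovered 36% of genes changed 1.15-fold, 89.6% at 1.3-fold, 99.6% at 1.5-fold and 100% at 2-fold, and called 0.0656% of unchanged genes. For ipatasertib against DMSO it recovered 35.6%, 89.6%, 98.8% and 100%, and called 0.0762%. Changes much below 1.3-fold were therefore often missed at this spread when 200 genes changed. The adjusted threshold is looser where more genes change, so these shares do not carry over to the real I-BRD9 comparison. There 6493 genes passed, with a median absolute log2 fold change of 0.267.

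Shared DMSO libraries were handled by 100 simulations of unchanged groups. Gene calls, from limma fits with 4 groups and 5 residual degrees of freedom, and the covariance of fold changes were also computed with separate DMSO libraries, 1 for one treatment and the other 2 for the other, in all 6 ways, the covariance beside 100 simulations with the I-BRD9 effects kept and ipatasertib without effect, a step added after the data were seen. Ranges of the list tests cover the settings of camera, and leave out fry. Alternatives fixed beforehand were pseudocounts of 0.1 and 5, no filter or a mean of at least 5 FPKM, median-ratio scaling, quantile normalization, limma without the trend, the 6 libraries of a comparison alone, the replicate number as a block, each library left out in turn, an estimated correlation and fry. Removal of each library's trend with GC content and length by local regression, and scaling to an equal total FPKM, were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.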

Results

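The transcriptome of MDA-MB-231 cells, a human line of triple-negative breast cancer, was measured by RNA sequencing after 16 h of treatment. The cells received the solvent DMSO, I-BRD9, a small molecule that binds the bromodomain of BRD9, or ipatasertib, an inhibitor of the AKT kinases. There were 3 libraries per treatment and 9 in all, and the labels give no dose. Messenger RNA was selected by its poly-A tail, and expression was given as FPKM (fragments per length of transcript, scaled to the mapped fragments of the library) for 17219 genes. The sum over genes lay between 569606 and 625265 FPKM per library. The number of fragments per library is unknown, but the steps that single reads leave in low histone genes put the depths of the libraries, relative to each other, between 0.962 and 1.037. Across genes, libraries of the same treatment correlated with a Pearson r of 0.997 to 0.999. The root mean square difference of log2 values was 0.0828 to 0.143 within a treatment, 0.105 to 0.142 between DMSO and ipatasertib libraries, and 0.290 to 0.320 between DMSO and I-BRD9 libraries. MT2A, which encodes a metal-binding metallothionein, supplied 1.18% to 1.56% of all FPKM in the DMSO libraries and 3.04% to 3.25% in the I-BRD9 libraries. Nothing in the labels says whether the libraries of a treatment came from separate cultures, so the p-values measure the spread between these libraries only.

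The series links BRD9, as a reader of methylated arginine, with signalling through AKT and EZH2, so the genes of that route were examined first. EZH2 (gene ID 2146, chromosome 7 from 148807383 to 148884321 in GRCh38), the catalytic subunit of the repressive Polycomb complex PRC2, was at 36.7 ± 2.47 FPKM with DMSO (mean ± SD, n = 3) and 1.54-fold lower with I-BRD9, at 23.9 ± 1.88 FPKM (adjusted p = 1.22e-06). With ipatasertib it was at 36.9 ± 0.61 FPKM, a log2 fold change of 0.01 ± 0.06 (SE, adjusted p = 0.968), and the difference between the treatments was itself past the threshold (log2 difference -0.61 ± 0.06, adjusted p = 1.08e-06). In that contrast the median log2 differences of the G1/S and G2/M gene lists were -0.47 and -0.55, so a difference of about this size was not particular to EZH2. The other core subunits EED and SUZ12 fell by 0.22 ± 0.04 and 0.19 ± 0.06 on the log2 scale with I-BRD9, and PRMT5, an arginine methyltransferase, fell by 0.20 ± 0.04. With ipatasertib the log2 fold changes of EED, SUZ12 and PRMT5 were -0.05 ± 0.04, 0.00 ± 0.06 and -0.10 ± 0.04, none past the threshold. BRD9 (gene ID 65980, chromosome 5 from 850291 to 892824), a subunit of the non-canonical SWI/SNF chromatin remodelling complex, was at 23.7 ± 0.471 FPKM with DMSO, 22.5 ± 0.452 FPKM with I-BRD9 and 23.8 ± 0.94 FPKM with ipatasertib, and neither comparison passed (adjusted p = 0.151 and 0.971). Against DMSO, BRD9 was lower with I-BRD9 and past the threshold under median-ratio scaling (log2 fold change -0.11, adjusted p = 0.0426) and with an equal total FPKM (-0.13, 0.0325), within a range of 0.0325 to 0.345 over the settings, so whether its level changed depends on the scaling. Its relative BRD7 had log2 fold changes of -0.01 ± 0.04 and 0.02 ± 0.04, and neither passed. AKT1 and AKT2, kinases that ipatasertib blocks, were at 88.4 ± 1.46 and 50.4 ± 1.72 FPKM with DMSO and passed in neither comparison (adjusted p of 0.44 or more). The I-BRD9 call for SUZ12 was lost without DMSO replicate 3 (adjusted p = 0.0564, the highest of a range from 0.00129).

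The first comparison asked which transcripts I-BRD9 changed against DMSO. On the log2(FPKM + 1) scale the highest fold changes included those of histone genes: H4C15 rose 4.71-fold, from 6.83 ± 1.29 to 32.1 ± 1.07 FPKM (SD, n = 3), H2BC5 rose 3.42-fold, from 21.1 ± 0.599 to 72.3 ± 7.96 FPKM, and H2AC18 rose 3.61-fold, from 41.5 ± 3.54 to 149.6 ± 13.4 FPKM. SERPINI1, a neuronal serine protease inhibitor, rose 4.28-fold, and DCXR, a reductase of sugars and dicarbonyls, rose 3.05-fold, from 38.6 ± 1.94 to 117.7 ± 2.26 FPKM. The chemerin receptor gene CMKLR1 was 6.59-fold lower, at 10.3 ± 0.647 FPKM with DMSO and 1.57 ± 0.135 FPKM with I-BRD9. SPDEF, a transcription factor of luminal epithelial cells, was 9-fold lower (6.57 ± 0.685 against 0.73 ± 0.0819 FPKM). Of 11483 genes tested with limma, 6493 (56.5%) changed, 3760 higher and 2733 lower, and on the log2(FPKM + 1) scale 628 of these changed by at least 0.58, 278 higher and 350 lower. By at least 1 log2 unit, 37 genes were higher and 45 lower. The 3 libraries of each group did not overlap in 59.7% of genes, where chance gives 10%. With every library scaled to the same total FPKM, 2629 genes were higher and 3504 lower, so the balance of directions rests on the scaling. H4C15 and H4C14 encode the same protein from near-identical copies, as H2AC18 does with its neighbouring copy, so reads shared between copies leave their single values uncertain.

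**Figure D1:**
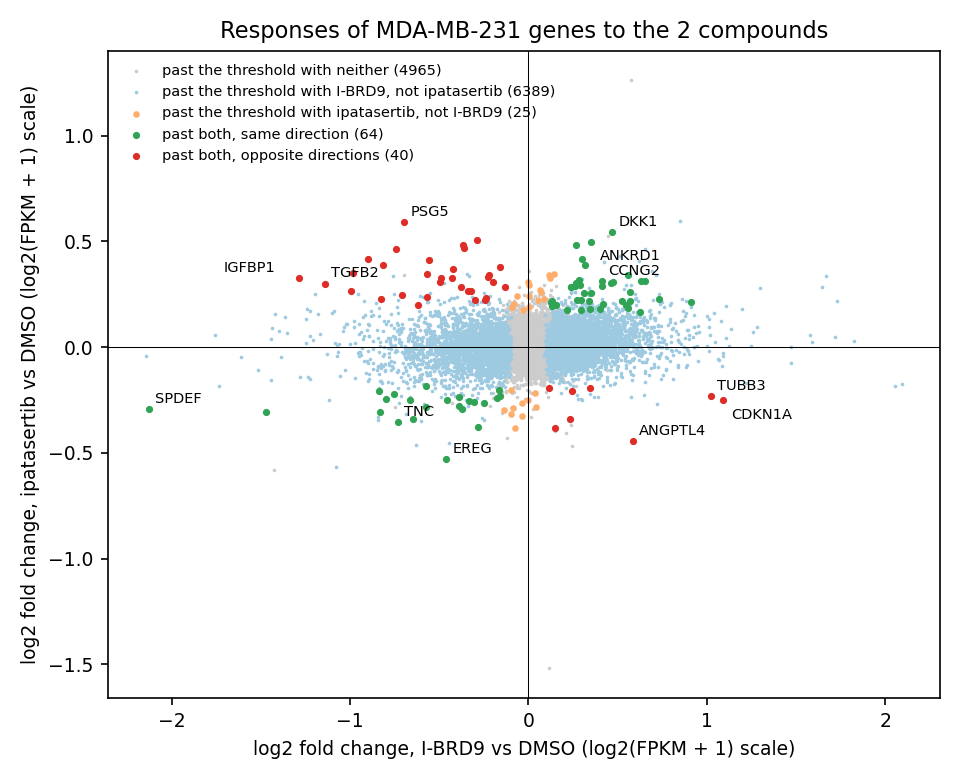
Log2 fold change of each of the 11483 tested genes with ipatasertib (vertical axis) against that with I-BRD9 (horizontal axis), each against 3 DMSO libraries, on the log2(FPKM + 1) scale; each point is 1 gene, coloured by the comparisons it passed. The points spread along the horizontal axis, with 6493 genes past the threshold for I-BRD9 and 129 for ipatasertib.

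Genes of the cell division cycle fell with I-BRD9. Of 28 measured genes of G2/M and mitosis, 27 fell, 0 rose and 1 was not past the threshold (27 fell adjusted over the list alone). TOP2A, the topoisomerase that untangles mitotic chromosomes, went from 139.3 ± 5.92 to 83.0 ± 2.35 FPKM (n = 3, adjusted p = 1.37e-08), CCNA2, which encodes cyclin A, was 1.72-fold lower, and the mitotic kinase gene AURKA was 1.59-fold lower. Of 30 genes of G1/S and DNA replication, 27 fell and 1 rose, with the same numbers adjusted over the list alone. MCM2, a subunit of the replicative helicase, was 1.60-fold lower (61.2 ± 0.724 against 38.2 ± 2.27 FPKM), and CDC45, which activates that helicase, was 1.72-fold lower. CDKN1A, the gene of the cyclin-dependent kinase inhibitor p21, rose 2.15-fold, from 51.4 ± 3.13 to 110.4 ± 1.86 FPKM. Against all other tested genes, camera gave an adjusted p of 2.38e-15 for the G2/M list and 5.48e-14 for the G1/S list, and an adjusted p = 0.311 for each with an estimated correlation. With ipatasertib, 0 of 28 and 0 of 30 members passed limma's threshold, also adjusted over the list alone (camera adjusted p = 0.13 and 0.312, and 0.955 and 0.993 with an estimated correlation). The G2/M list passed for ipatasertib without DMSO replicate 3 (0.0354) and with quantile normalization (0.0299). In each case it passed as higher and not lower, with a median log2 fold change of 0.04 as reported.

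Replication-dependent histone genes, whose main transcripts end without a poly-A tail, went the other way. Of the 15 with a tested value, 10 rose, 0 fell and 5 were not past the threshold, with the same numbers adjusted over the list alone. H2AC6 rose from 24.5 ± 3.25 to 79.9 ± 7.62 FPKM and H2BC21 from 1.68 ± 0.0451 to 7.06 ± 0.973 FPKM (SD, n = 3), and the median log2 fold change of the list was 0.61. Among those that did not pass were H1-4 and H3C3, with log2 fold changes of -0.02 ± 0.15 and 0.12 ± 0.18. Camera gave an adjusted p of 0.000683, and an adjusted p = 0.311 with an estimated correlation. Since RNA was selected by poly-A tails, these values cover only histone transcripts that were retained by that selection.

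Genes of cholesterol synthesis and uptake rose with I-BRD9, 20 of 25, while 3 fell (21 and 3 adjusted over the list alone). TM7SF2, a sterol reductase, rose 2.62-fold, from 6.42 ± 0.148 to 16.8 ± 0.852 FPKM, and DHCR7, which makes cholesterol in the last step of the pathway, rose 1.96-fold, from 27.2 ± 0.247 to 53.3 ± 4.48 FPKM (SD, n = 3). The camera adjusted p was 9.29e-05, and the adjusted p = 0.311 with an estimated correlation. Targets of FOXO, transcription factors that AKT keeps inactive, also rose: 15 of 29 were higher and 2 lower, with the same numbers adjusted over the list alone. TXNIP, an inhibitor of thioredoxin and glucose uptake, rose 2.40-fold, from 66.9 ± 5.87 to 160.2 ± 10.7 FPKM, and the catalase gene CAT rose 1.52-fold. SESN3, which encodes a sestrin that restrains mTORC1, rose 4.73-fold from a low level, 0.477 ± 0.0643 to 2.26 ± 0.346 FPKM. For the FOXO list the camera adjusted p was 0.0061, with an adjusted p = 0.311 with an estimated correlation, and it was 0.0736 among genes with a mean of at least 5 FPKM, within a range of 0.00129 to 0.311 over the camera settings. Of 29 autophagy and lysosome genes, 13 rose and 2 fell, with the same numbers adjusted over the list alone, and SQSTM1, the receptor p62 that delivers cargo to autophagosomes, rose 1.84-fold, from 499.1 ± 40.9 to 916 ± 31.6 FPKM. That list missed the threshold (camera adjusted p = 0.0636, and adjusted p = 0.311 with an estimated correlation), but passed among genes with a mean of at least 5 FPKM (0.0364).

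Several groups tied to the cell surface, matrix and interferon response were lower with I-BRD9. Of 34 genes of extracellular matrix and invasion, 24 fell and 4 rose (26 and 4 adjusted over the list alone). TIMP3, an inhibitor of matrix metalloproteinases, was 2.62-fold lower (99.9 ± 2.26 against 38.2 ± 1.64 FPKM, n = 3), and THBS1, the matrix protein thrombospondin, was 1.91-fold lower. Of 30 interferon-stimulated genes, 20 fell and 5 rose, with the same numbers adjusted over the list alone. OASL, an antiviral protein, was 2.14-fold lower (32.8 ± 2.00 against 15.3 ± 1.81 FPKM), whereas IRF7, a transcription factor that drives interferon genes, rose 2.30-fold. Developmental regulators of the Polycomb type, a class often silenced by PRC2, fell in 12 of 19 cases and rose in 1, with the same numbers adjusted over the list alone, and WNT7B, a secreted signalling protein, was 1.54-fold lower. Of the 49 listed regulators, 23 were below the expression filter. The 19 tested were thus expressed in these cells, and their fall does not measure silencing by PRC2. Of 25 ribosome biogenesis genes, 13 fell and 2 rose (16 and 2 adjusted over the list alone), among them RRS1, a ribosome assembly factor, at 30.5 ± 1.85 FPKM with DMSO and 23.2 ± 0.0851 FPKM with I-BRD9. The camera adjusted p was 6.67e-07 for matrix genes, 0.000273 for interferon genes, 0.0061 for developmental regulators and 0.0026 for ribosome biogenesis. With an estimated correlation these became an adjusted p = 0.311, 0.311, 0.313 and 0.311.

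In 5 further lists the call for I-BRD9 depended on single libraries. Processing mattered too: of the 15 lists that passed for I-BRD9, 3 were lost under median-ratio scaling, 4 with an equal total FPKM and 3 with the GC and length trend removed. In these settings 1, 2 and 1 others passed. With the replicate number as a block 4 were lost, and with a pseudocount of 5 FPKM 3, while 0 others passed. ATF4 targets, genes of the amino acid stress response, fell in 16 of 28 cases and rose in 6, with the same numbers adjusted over the list alone, among them GDF15, a stress-induced cytokine, which was 2.09-fold lower, and the asparagine synthetase gene ASNS, which rose by 0.52 ± 0.06 on the log2 scale (camera adjusted p = 0.0187, 0.0613 without DMSO replicate 1, range 0.00461 to 0.551). YAP targets fell in 10 of 20 cases and rose in 4, with the same numbers adjusted over the list alone, and TGFB2, a growth factor of the TGF-beta family, was 2.30-fold lower (camera adjusted p = 0.0419, 0.0663 without DMSO replicate 3 and 0.064 without I-BRD9 replicate 1, range 0.0237 to 0.311). Glycolysis genes rose in 15 of 21 cases and fell in 2, mesenchymal regulators fell in 7 of 10 cases and rose in 2, and nuclear-encoded genes of oxidative phosphorylation rose in 13 of 30 cases and fell in 1, each with the same numbers adjusted over the list alone. The glycolytic aldolase genes ALDOA and ALDOC rose by 0.33 ± 0.05 and 0.57 ± 0.07, and the growth factor gene TGFB1 rose by 0.50 ± 0.05, against the direction of the mesenchymal list. Each of these 3 lists had a camera adjusted p of 0.049, and it rose to 0.0501, 0.0519 and 0.0523 for glycolysis and mesenchymal regulators, or 0.0501, 0.0519 and 0.0518 for oxidative phosphorylation, without ipatasertib replicate 1, 2 or 3. The glycolysis call was also lost without DMSO replicate 3 (0.0807), I-BRD9 replicate 1 (0.056) or I-BRD9 replicate 2 (0.065). The mesenchymal call was also lost without DMSO replicate 1 (0.068), DMSO replicate 3 (0.0615), I-BRD9 replicate 1 (0.056) or I-BRD9 replicate 3 (0.0703), and the call for oxidative phosphorylation without the same libraries (0.0667, 0.0663, 0.056 and 0.108). With an estimated correlation the adjusted p = 0.551 for ATF4 targets, 0.311 for YAP targets, 0.317 for glycolysis, 0.311 for mesenchymal regulators and 0.554 for oxidative phosphorylation, which are the highest values of their ranges.

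The remaining lists missed the threshold for I-BRD9 as analysed, although single members changed and some lists passed in other settings. Among 12 PRC2 subunits 2 rose and 6 fell (camera adjusted p = 0.145, and 0.403 with an estimated correlation). Among 13 genes reported as repressed by EZH2, 3 rose and 4 fell, led by TIMP3 and by VASH1, an inhibitor of angiogenesis, which rose 2.19-fold (adjusted p = 0.33, and 0.554 with an estimated correlation). Among 24 members of the PI3K-AKT-mTOR pathway 9 rose and 3 fell (8 and 3 adjusted over the list alone, camera adjusted p = 0.553), among 25 SWI/SNF subunits 5 rose and 2 fell (4 and 2 adjusted over the list alone, 0.702), and among 11 arginine methyltransferase genes 2 rose and 3 fell (0.74). Hypoxia genes rose in 12 of 19 cases and fell in 4 (13 and 4 adjusted over the list alone, 0.0534), among them ANKRD37, a hypoxia-induced gene, which rose 2.04-fold. MHC class I genes fell in 7 of 15 cases and rose in 1 (0.0636), NF-kB and cytokine genes rose in 7 and fell in 9 of 22 (0.14), and the cytokine gene IL1A was 2.75-fold lower. For p53 targets the numbers were 9 higher and 6 lower of 19 (0.595), for MAPK output 9 and 6 of 21 (0.579), for epithelial genes 6 and 9 of 18 (0.191), and for the BCL2 family 3 and 6 of 14 (0.468). For endoplasmic reticulum chaperones they were 9 and 1 of 18 (0.106), for cytosolic heat shock proteins 1 and 5 of 16 (0.203), and for fatty acid synthesis 7 and 2 of 15 (0.29). Where no second count is given, the count adjusted over the list alone was the same. The hypoxia list depended on the setting: it passed under median-ratio scaling (0.0449), quantile normalization (0.0491) and an equal total FPKM (0.0308), among genes with a mean of at least 5 FPKM (0.0167) and without DMSO replicate 2 (0.0298). MHC class I genes passed as lower with the GC and length trend removed (0.0198) and with an equal total FPKM (0.046). Genes reported as repressed by EZH2 passed among genes with a mean of at least 5 FPKM (0.0364), as lower with I-BRD9 and not as higher. With no filter, chaperones passed as higher (0.0472) and epithelial genes as lower (0.0419). With an estimated correlation these lists had adjusted p values between 0.313 and 0.812. The bromodomain and extra-terminal (BET) genes with HEXIM1 and SERPINI1 rose in 3 of 5 cases and fell in 1 (4 and 1 adjusted over the list alone, camera adjusted p = 0.0876, and 0.311 with an estimated correlation), and BRD2, a BET protein, rose 1.49-fold.

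Lists that speak to RNA quality and to other cells were read beside these groups. Of 36 ribosomal protein genes, 5 rose and 2 fell with I-BRD9 (2 and 0 adjusted over the list alone, camera adjusted p = 0.99, and 0.997 with an estimated correlation), with a median log2 fold change of 0.02. Of 8 luminal breast markers with a tested value, 7 fell and 1 rose, also adjusted over the list alone, including the keratin gene KRT8 at 274.8 ± 6.10 FPKM with DMSO and 188.6 ± 7.17 FPKM with I-BRD9 (SD, n = 3; camera adjusted p = 0.000986, and adjusted p = 0.311 with an estimated correlation). Among blood cell markers CD14 and CD68, a monocyte receptor and a lysosomal protein of macrophages, fell by 0.83 ± 0.06 and 0.29 ± 0.05, and among fibroblast markers the collagen gene COL1A1, at 3.11 FPKM with DMSO, fell by 0.23 ± 0.07. Of the genes reported to respond to I-BRD9 in Kasumi-1 leukaemia cells, DUSP6, a phosphatase that restrains ERK, had a tested value and rose by 0.33 ± 0.14 (adjusted p = 0.0496). These 3 lists held too few tested genes for a list test, and the 13 mitochondrially encoded genes were not analysed here.

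**Figure D2:**
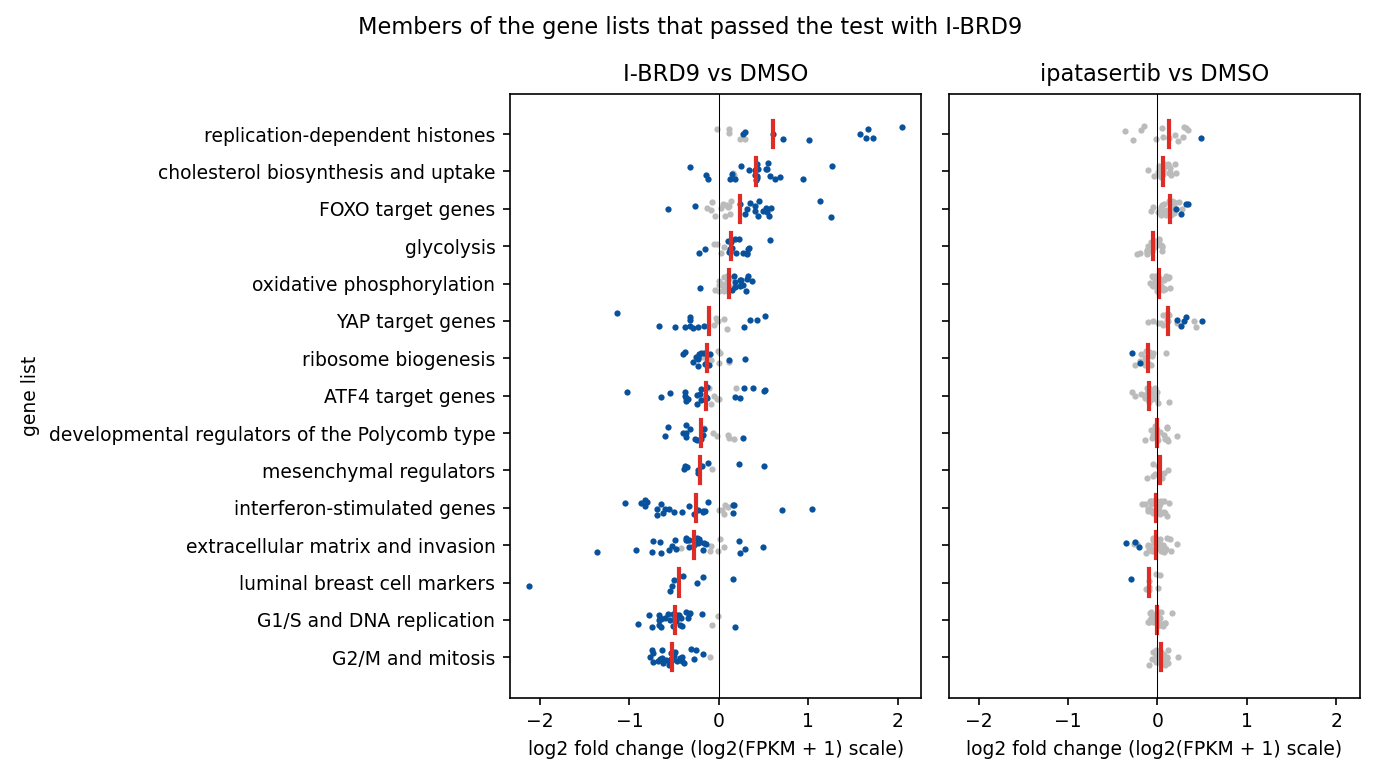
Log2 fold changes, on the log2(FPKM + 1) scale, of the members of the 15 gene lists that passed the camera test with I-BRD9, for I-BRD9 (left) and ipatasertib (right) against DMSO; each point is 1 gene, blue where it passed the genome-wide threshold, and red bars are list medians. The medians for I-BRD9 run from -0.53 for G2/M and mitosis to 0.61 for histones, and those for ipatasertib lie closer to 0 except for YAP targets (0.12 against -0.11).

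The second comparison asked which transcripts the AKT inhibitor changed. EREG and AREG, ligands of the epidermal growth factor receptor, were 1.52-fold and 1.33-fold lower with ipatasertib, at 8.68 ± 0.481 against 5.70 ± 0.154 FPKM and 18.3 ± 0.455 against 13.8 ± 0.725 FPKM (SD, n = 3, adjusted p = 0.00163 and 0.00459). VEGFA, the vascular growth factor, and TNC, a matrix glycoprotein, were 1.31-fold and 1.28-fold lower. DKK1, a secreted inhibitor of Wnt signalling, rose 1.46-fold, from 78.7 ± 5.91 to 115 ± 1.35 FPKM (adjusted p = 0.00311). The pregnancy-specific glycoprotein genes PSG1, PSG4 and PSG5 rose 1.51-fold, 1.58-fold and 1.75-fold from DMSO levels of 3.66, 2.00 and 2.05 FPKM, and since these copies are closely related, reads shared between them leave the single values uncertain. EREG, AREG, VEGFA, TNC, DKK1 and the 3 PSG genes were among 15 of 48 named calls that held wherever they were tested. At a mean of at least 5 FPKM, a filter that drops low genes, 78 of 93 named genes were tested. Named genes were not examined with the 6 libraries of this comparison alone or with separate DMSO libraries. In all, 129 genes changed, 88 higher and 41 lower, 0 of them by 1 log2 unit or more, with 1622 genes at an unadjusted p under 0.05. The highest absolute log2 fold change among the 129 was 0.59, and libraries did not overlap in 23.5% of genes, where chance gives 10%. The count fell to 37, 44 and 73 without DMSO replicates 1, 2 and 3, and to 30, 24 and 38 without ipatasertib replicates 1, 2 and 3. It was 41 with no filter on low genes, and 235 from the 6 libraries of this comparison alone. With quantile normalization 81 genes were higher and 59 lower.

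FOXO targets rose with ipatasertib in 4 of 29 cases and fell in 0, and 14 rose adjusted over the list alone. RBL2, a pocket protein that restrains cell cycle entry, rose 1.22-fold, from 9.44 ± 0.139 to 11.5 ± 0.356 FPKM, and KLHL24, a ubiquitin ligase adaptor, rose 1.32-fold (SD, n = 3). CDKN1B, the gene of the cyclin-dependent kinase inhibitor p27, rose 1.16-fold, from 20.2 ± 1.00 to 23.3 ± 0.182 FPKM (adjusted p = 0.0425). Targets of YAP, a transcriptional regulator that responds to tension and cell contact, rose in 5 of 20 cases and fell in 0, and 10 rose adjusted over the list alone. GADD45B, a stress-response gene, rose 1.25-fold, and ANKRD1, a cardiac ankyrin repeat protein that YAP induces in many cells, rose 1.41-fold, from 196.5 ± 17.9 to 277.6 ± 14.8 FPKM. Of 25 ribosome biogenesis genes, 2 fell and 0 rose, and 12 fell adjusted over the list alone. RRP9, which binds U3 small nucleolar RNA, was lower, at 32.8 ± 1.31 FPKM with DMSO and 28.5 ± 0.388 FPKM with ipatasertib. Camera gave an adjusted p of 1.04e-08 for FOXO targets, 1.04e-08 for YAP targets and 8.95e-13 for ribosome biogenesis, and with an estimated correlation an adjusted p = 0.128, 0.0836 and 0.0836. Several of these gene calls rested on single libraries. Without DMSO replicates 1, 2 and 3 and then ipatasertib replicates 1, 2 and 3, the adjusted p was 0.0681, 0.0583, 0.0529, 0.113, 0.06 and 0.0675 for RBL2, 0.0834, 0.087, 0.0648, 0.103, 0.108 and 0.0824 for KLHL24, and 0.139, 0.087, 0.0716, 0.153, 0.169 and 0.114 for RRP9. Without DMSO replicates 1 and 2 and then ipatasertib replicates 1, 2 and 3 it was 0.139, 0.108, 0.141, 0.159 and 0.152 for CDKN1B and 0.119, 0.0911, 0.0548, 0.104 and 0.111 for ANKRD1. Without ipatasertib replicate 2 it was 0.0573 for GADD45B.

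In 9 other lists that passed camera with ipatasertib, few or no members passed by themselves. ATF4 targets and cytosolic heat shock proteins had 0 members past limma's threshold, also adjusted over the list alone, and median log2 fold changes of -0.09 and -0.06 (camera adjusted p = 1.54e-06 and 0.000106, and an adjusted p = 0.342 for each with an estimated correlation). TRIB3, a pseudokinase induced by ATF4, was at 18.7 ± 1.99 FPKM with DMSO and 15.2 ± 0.435 FPKM with ipatasertib (n = 3, adjusted p = 0.145). Glycolysis genes had 0 past the threshold, with 2 lower adjusted over the list alone (0.00528, and an adjusted p = 0.33 with an estimated correlation), among them HK2, a hexokinase that AKT signalling supports, at 17.9 ± 1.11 against 15.2 ± 0.321 FPKM (adjusted p = 0.0508). HK2 passed without DMSO replicate 3 (0.0458), I-BRD9 replicate 2 (0.0396) or I-BRD9 replicate 3 (0.039). Cholesterol genes had 0 past the threshold and a median of 0.07 (0.00528, 0.0547 without DMSO replicate 1, range 0.000593 to 0.605), and autophagy and lysosome genes had 1 that rose, GABARAPL1, an ATG8 family protein (0.0106, 0.0642 without ipatasertib replicate 3, range 0.00268 to 0.272). Of luminal markers SPDEF fell (0.00652, and 0.35 with an estimated correlation), and of genes reported as repressed by EZH2 DKK1 rose, with 2 higher adjusted over the list alone (0.0119, and 0.272 with an estimated correlation). Chaperones of the endoplasmic reticulum and ribosomal proteins had 0 past the threshold and medians of -0.03 and -0.01 (both 0.0471, and 0.663 and 0.919 with an estimated correlation). The chaperone call was lost without DMSO replicate 1 (0.0664), DMSO replicate 2 (0.379), I-BRD9 replicate 2 (0.0501) or ipatasertib replicate 3 (0.281), and the ribosomal protein call without DMSO replicate 1 (0.578), I-BRD9 replicate 1 (0.0552), I-BRD9 replicate 2 (0.0508) or ipatasertib replicate 1 (0.335). The adjusted p with an estimated correlation was 0.605 for cholesterol genes and 0.272 for autophagy genes, and where no second count is given, the count adjusted over the list alone was the same. Without DMSO replicates 1, 2 and 3 and then ipatasertib replicates 1, 2 and 3, the adjusted p was 0.175, 0.108, 0.0689, 0.0831, 0.208 and 0.165 for GABARAPL1 and 0.173, 0.101, 0.0545, 0.16, 0.125 and 0.18 for SPDEF, which also passed no longer without I-BRD9 replicate 1 (0.0538). The other 21 tested lists did not pass camera, PRC2 subunits, PI3K-AKT-mTOR members and SWI/SNF subunits with 0 members past the threshold among them. Of these 21, interferon-stimulated genes passed as lower without DMSO replicate 1 (0.0203) or ipatasertib replicate 2 (0.0399). Histone genes passed as higher without DMSO replicate 1 (0.0203), and matrix genes as lower without DMSO replicate 2 (0.0351).

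The third comparison set the treatments against each other, without use of the DMSO libraries in the contrast. Cell cycle genes were lower with I-BRD9 than with ipatasertib, 28 of 28 for G2/M and 28 of 30 for G1/S, where 1 was higher, with the same numbers adjusted over the list alone (camera adjusted p = 3.12e-16 and 1.35e-13). YAP targets were lower in 13 of 20 cases and higher in 0, also adjusted over the list alone (0.000102), and of these TGFB2 was at 12.1 ± 0.896 FPKM with I-BRD9 and 34.6 ± 1.13 FPKM with ipatasertib (SD, n = 3). Matrix genes were lower in 21 and higher in 4 of 34 cases (22 and 5 adjusted over the list alone, 1.42e-05), interferon-stimulated genes lower in 19 and higher in 4 of 30 (19 and 5 adjusted over the list alone, 0.000347), and cholesterol genes higher in 20 and lower in 3 of 25 (0.000492). With an estimated correlation the adjusted p = 0.327 for the cell cycle, YAP, matrix and interferon lists and 0.344 for cholesterol genes. FOXO targets did not pass this contrast, with 13 higher and 6 lower of 29 (13 and 8 adjusted over the list alone, camera adjusted p = 0.302, and 0.759 with an estimated correlation). Histone genes were higher in 9 of 15 cases and lower in 0 (0.00372), luminal markers lower in 7 of 8 and higher in 1 (0.00372), and developmental regulators of the Polycomb type lower in 13 of 19 and higher in 2 (0.00493). Glycolysis genes were higher in 13 of 21 cases and lower in 1 (0.00493), and hypoxia genes higher in 12 of 19 and lower in 3 (0.0221). For these 5 lists the adjusted p with an estimated correlation lay between 0.327 and 0.367. Chaperones of the endoplasmic reticulum were higher in 10 of 18 cases and lower in 1 (0.0492, range 0.0202 to 0.522, the highest with an estimated correlation), and passed no longer without I-BRD9 replicate 1 (0.0662), I-BRD9 replicate 3 (0.0539), ipatasertib replicate 1 (0.0508) or ipatasertib replicate 3 (0.0925). Where no second count is given, that adjusted over the list alone was the same. With no filter on low genes, 3 of the 12 lists that passed camera in this contrast were lost and 4 others passed. Among genes with a mean of at least 5 FPKM, 2 were lost and 1 other passed. IGFBP1, which binds insulin-like growth factors, had a log2 difference of -1.61 ± 0.06 (7.04 ± 0.586 against 23.6 ± 1.38 FPKM), and APOBEC3G, an antiviral cytidine deaminase, had a log2 difference of -1.58 ± 0.11. In all 6367 genes differed, 3566 higher and 2801 lower with I-BRD9, and with every library scaled to the same total FPKM 2482 were higher and 3524 lower. Groups did not overlap in 61.5% of genes, where chance gives 10%.

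**Figure D3:**
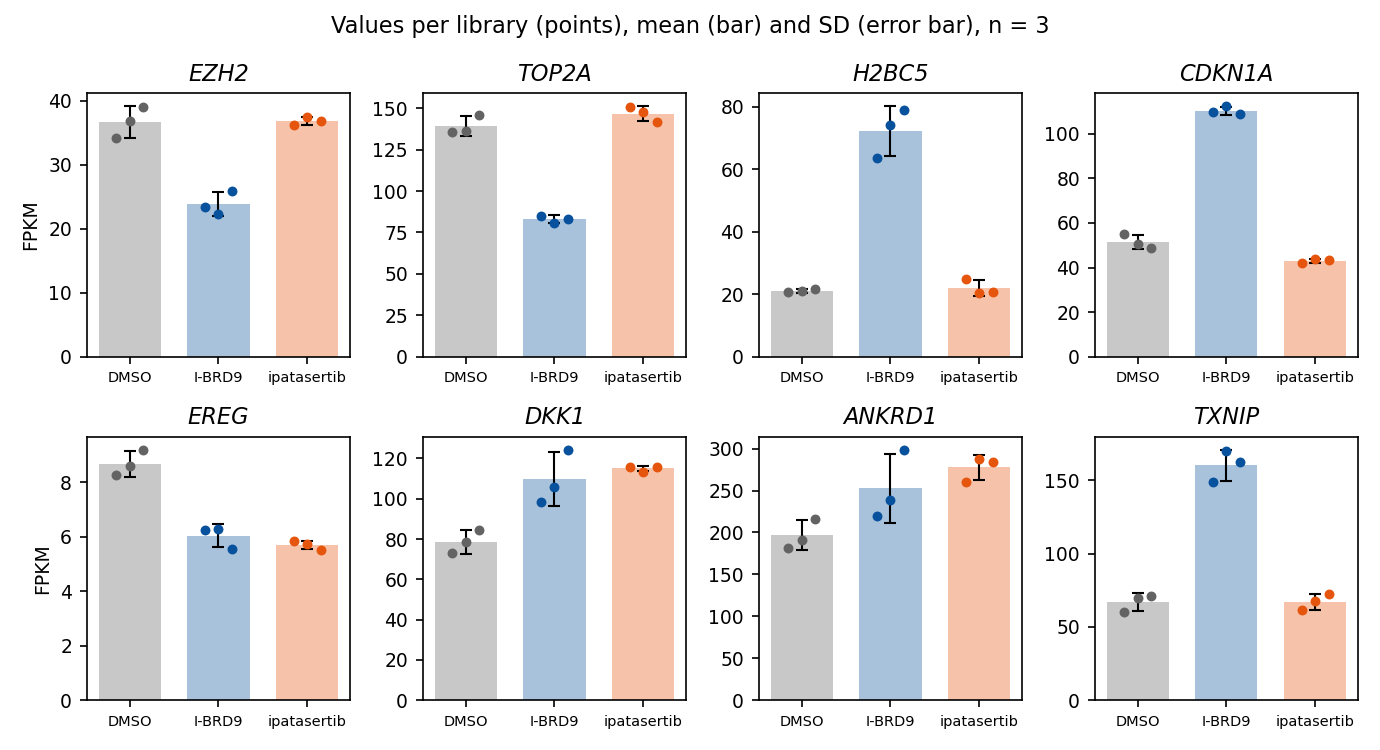
FPKM of 8 genes in the 3 libraries of each treatment; points are libraries, bars are means and error bars are SD (n = 3). EZH2 and TOP2A were lower and H2BC5, CDKN1A and TXNIP higher with I-BRD9, while EREG was lower and DKK1 and ANKRD1 higher with each compound.

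The last question was how far the responses met. Of the 129 genes that changed with ipatasertib, 104 also changed with I-BRD9, 64 in the same direction and 40 in the opposite one. Higher with each were DKK1 (1.39-fold with I-BRD9 and 1.46-fold with ipatasertib), NMT2, a protein N-myristoyltransferase (1.39-fold and 1.24-fold), and UGCG, which makes glucosylceramide (1.25-fold and 1.31-fold). Lower with each were EREG (1.44-fold and 1.52-fold), TNC (1.68-fold and 1.28-fold) and VEGFA (1.22-fold and 1.31-fold). In the opposite direction, CDKN1A rose 2.15-fold with I-BRD9 and was 1.20-fold lower with ipatasertib, and TUBB3, a neuronal beta-tubulin, rose 2.04-fold and was 1.18-fold lower. The reverse held for TGFB2, IGFBP1, COL8A1, a short-chain collagen of vessel walls, and FST, the activin-binding protein follistatin, which were 2.30-fold, 2.64-fold, 2.08-fold and 2.26-fold lower with I-BRD9 and rose 1.24-fold, 1.27-fold, 1.29-fold and 1.40-fold with ipatasertib. Of the 64 genes with the same direction, 32 did not pass in the direct contrast between the treatments. Some ipatasertib calls among these were lost without single libraries. Without DMSO replicates 1 and 2 and then ipatasertib replicates 1, 2 and 3, the adjusted p was 0.0568, 0.0529, 0.113, 0.068 and 0.0675 for CDKN1A and 0.11, 0.0895, 0.115, 0.119 and 0.0662 for TGFB2. Without DMSO replicates 1 and 3 and then ipatasertib replicates 1, 2 and 3 it was 0.0567, 0.0529, 0.0904, 0.069 and 0.0665 for TUBB3, and without DMSO replicates 1, 2 and 3 and then ipatasertib replicates 2 and 3 it was 0.0514, 0.0985, 0.0582, 0.1 and 0.114 for IGFBP1. For FST it was 0.0593 without ipatasertib replicate 2 and 0.0608 with no filter on low genes, and for UGCG 0.054 with no filter.

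Independent lists of these sizes would share 28.8 genes higher with each treatment, where 41 were found, and 9.76 lower with each, where 23 were found. They would share 20.9 genes lower with I-BRD9 and higher with ipatasertib, where 32 were found, and 13.4 of the reverse, where 8 were found. Across the 11483 genes the fold changes correlated with a Pearson r of 0.171 and a Spearman rho of 0.199, where 100 simulations of unchanged groups against the same DMSO libraries averaged 0.492 and 0.472, which are not comparable, since the simulated groups lack the wide spread of real I-BRD9 effects. The covariance of the fold changes was 0.00437 against a simulated mean of 0.00197 (range -0.00089 to 0.00691), a difference of 0.0024. With separate DMSO libraries, 1 for one treatment and 2 for the other, the covariance averaged 0.00245 over the 6 ways to divide them (range -0.00039 to 0.00483) and r averaged 0.0907 (-0.0103 to 0.175). Genes are not independent replicates, so no p was computed. Gene calls with the same separate DMSO libraries averaged 19.8 shared in the same direction (0 to 61 over the 6 ways) where independent lists would share 13.4, and 18.7 in opposite directions (0 to 56) where they would share 12.1. Whether part of the excess with all DMSO libraries comes from the shared controls is not decided by these averages, since each such fit has fewer controls. Independent lists are also a rough yardstick, since both comparisons use the same estimate of spread for each gene. The number shared in the same direction fell to 16, 21 and 29 without DMSO replicates 1, 2 and 3 and to 10, 8 and 15 without ipatasertib replicates 1, 2 and 3. The number in opposite directions fell to 14 and 18 without DMSO replicates 1 and 2 and to 17, 12 and 16 without ipatasertib replicates 1, 2 and 3.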

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

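Removal of the GC content and length trend, the scaling to an equal total FPKM and the separate DMSO libraries were chosen only after the results were seen, and all other settings beforehand. Named genes and lists were not examined with the 6 libraries of a comparison alone or with separate DMSO libraries. Over the other settings 0 called genes or lists reversed. Of named calls, 158 of 165 for I-BRD9, 15 of 48 for ipatasertib and 27 of 29 for the direct contrast held wherever they were tested. At a mean of at least 5 FPKM, 147 of 169, 78 of 93 and 28 of 38 named genes, called or not, were tested. The FASN call for I-BRD9 ended when the GC and length trend was removed (adjusted p = 0.14, against 0.000252 as reported). The I-BRD9 count of 6493 stayed within 1.5 times in every setting, from 5840 to 6373 with 1 library left out and from 5059 to 7141 otherwise, and the direct count of 6367 from 5558 to 6526 and from 5001 to 6959. The correlation of fold changes, 0.171, ran from 0.144 to 0.217 with 1 library left out and averaged 0.0907 with separate DMSO libraries, which removes the shared chance values by construction but adds spread to each fold change. The ipatasertib count of 129 ran from 24 to 171 with 1 library left out. It was 41 with no filter, where more genes entered the adjustment, and 235 from its 6 libraries alone. These ranges of the I-BRD9 and ipatasertib counts leave out the fits with separate DMSO libraries, where 1 group held a single library. Genes changed the same way by both ran from 8 to 89 with 1 library left out (64 as reported), and were 15 with no filter, 104 with the GC and length trend removed and 19.8 on average with separate DMSO libraries. Those changed in opposite directions ran from 12 to 50 (40 as reported) and were 18 with no filter and 18.7 on average with separate DMSO libraries, where each fit has fewer controls. The cause of the other shifts was not tested. Lists past the test with 1 library left out numbered 11 to 16 for I-BRD9, 10 to 13 for ipatasertib and 11 to 14 for the direct contrast (15, 12 and 12 as reported). They fell to 0, 0 and 0 with an estimated correlation, and were 25, 5 and 23 with fry, which does not compare a list with other genes. Equal replicate numbers did not mark pairs: 3 of 9 correlations between same-numbered libraries were over 0.1, and although DMSO replicate 1 and I-BRD9 replicate 1 had the highest of all (0.307), 0 of 9 libraries correlated best with their own number in both other groups. With the replicate number as a block the counts were 6641, 150 and 6479 genes, 80 changed the same way by both and 44 in opposite directions, and 11 lists in each comparison passed, with a correlation of fold changes of 0.171. What depth limits cannot be given in reads, as absolute depth is unknown.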

Other observations

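The counts over the 10 splits and the 100 groupings and the 2 tests of DMSO libraries in shared use were fixed before their results were seen. The tests of the GC content and length trend, library scaling, S phase, RNA carry-over, BET proteins, separate DMSO libraries and groupings with the I-BRD9 libraries kept together, and the genes of this and the next paragraph, were chosen only afterwards. Genes of MHC class II antigen presentation were lower with I-BRD9: all 12 tested members fell and kept that call in the 3 other scalings. HLA-DRA, the alpha chain of HLA-DR, went from 233.3 ± 3.50 to 156.3 ± 6.17 FPKM (SD, n = 3), a log2 fold change of -0.58 ± 0.04, and HLA-DQA1 from 4.99 ± 0.438 to 2.84 ± 0.236 FPKM. With ipatasertib 3 of the 12 fell, HLA-DRA, HLA-DQB1 and HLA-DMB. Without DMSO replicates 1, 2 and 3 and then ipatasertib replicates 1 and 2, the adjusted p of HLA-DQB1 with ipatasertib was 0.113, 0.104, 0.0529, 0.138 and 0.116. Reads shared between HLA-DRB genes leave their single values uncertain. Genes of caveolae, small pits of the plasma membrane, fell with I-BRD9 in 5 of 5 cases, also in the 3 other scalings, with CAV1, the main coat protein, at 201.2 ± 9.90 FPKM with DMSO and 84.4 ± 1.29 FPKM with I-BRD9 and CAVIN2 at 15.1 ± 0.845 and 5.91 ± 0.332 FPKM. With ipatasertib CAV1 was at 227.9 ± 6.98 FPKM and CAVIN2 at 17.1 ± 0.238 FPKM, and 0 of the 5 passed.

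Tubulin genes parted in direction with I-BRD9: 6 of 10 rose and 3 fell, and all 9 calls held in the 3 other scalings. TUBA1A rose by 0.73 ± 0.05 on the log2 scale while TUBA1B, the most abundant member at 2018 ± 53.01 FPKM with DMSO, fell by 0.41 ± 0.05, and MAPT, the microtubule-binding protein tau, rose by 1.08 ± 0.05. Metallothionein genes rose in 4 of 6 cases and fell in 1, with MT2A going from 7735 ± 1218 to 18880 ± 1257 FPKM, and closely related copies again share reads. TXNRD1, a reductase of thioredoxin, and HMOX1, which breaks down haem, rose by 0.65 ± 0.04 and 0.81 ± 0.09, whereas NQO1, a quinone reductase often induced with them, fell by 0.30 ± 0.04. H4C12 was listed at 0 in ipatasertib replicates 1 and 2, where H4C11, a near-identical copy, was at 4.34 and 4.5 FPKM, and H4C11 was at 0 in the other 7 libraries, where H4C12 lay between 3.1 and 5.58 FPKM.

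Far more genes changed with I-BRD9 than with ipatasertib. Against a scaling artefact stands the count under the other scalings, at least 6133 for I-BRD9, and against a trend with GC content and length stand 6867 genes for I-BRD9 and 190 for ipatasertib once that trend was removed. The 6 libraries of a comparison allow only 10 splits, too few for a share under 0.05. In 1 of 10 splits, the real one, as many genes changed in each comparison: 6493 for I-BRD9 with at most 0 in another split, 129 for ipatasertib with at most 1, and 6367 between the treatments with at most 0. These counts decide nothing, since every other split mixes libraries of both groups, which raises the residual spread and gives few calls by design. Of the 10 splits, 4, 1 and 2 gave as many lists past camera (15, 12 and 12 in the real splits, at most 18, 9 and 13 in others), so the number of lists does not single out the real grouping for I-BRD9 or the direct contrast. The labels give no dose, so the numbers do not rank the targets by importance.

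Histone transcripts rose with I-BRD9 while replication genes fell, which argues against more cells in S phase, since 27 members of the G1/S list were lower. However, that fall was known when the test was set, and the share of cells in S phase was not measured. A trend with GC content and length is argued against as the whole cause, as 8 histones still rose with a median log2 fold change of 0.54 once that trend was removed, against 10 and 0.61 before. Carry-over of RNA without tails stays open: 5 of the 15 histones lay below the list's median by more than their 95% interval, but no other RNA without a tail was analysed here. Whether the compound also acts on BET bromodomains stays open. The 3 genes reported to respond to BET inhibitors rose (HEXIM1 by 0.23 ± 0.05, SERPINI1 by 1.73 ± 0.07 and BRD2 by 0.57 ± 0.04). However, they were picked for this test, from a list of 5 fixed beforehand, once the rise of SERPINI1 was known. In that list 3 rose and 1 fell (camera adjusted p = 0.0876), so this does not support that hypothesis.

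The fold changes of the treatments had a weak correlation (r of 0.171) and a covariance of 0.00437, against a mean of 0.00197 over simulations of unchanged groups, and genes shared in the same direction outnumbered those of independent lists, as did genes lower with I-BRD9 and higher with ipatasertib (32 against 20.9). With separate DMSO libraries the shared numbers averaged 19.8 in the same and 18.7 in opposite directions. Without any 1 of the DMSO libraries the covariance was 0.00488 at the lowest. This does not decide whether a single DMSO library was out of line, since fewer shared controls raise the covariance that chance values bring. With separate DMSO libraries the covariance ran from -0.00039 to 0.00483, depending on how they were divided. The chance values of the shared DMSO libraries stay a candidate explanation, since 8 of 100 simulations of unchanged groups reached the covariance, and with separate DMSO libraries 15 of 100 simulations with the I-BRD9 effects kept reached the mean of 0.00245. For the number of shared genes, 3 of 100 drawn groupings of the 9 libraries gave 64 or more (at most 5394 in another, where the 3 I-BRD9 libraries served as the control, a structure of the samples), but this decides nothing, since a grouping that mixes I-BRD9 libraries with others raises the residual spread and so gives few calls by design. With the I-BRD9 libraries kept together, 2 of 20 groupings gave as many (64, and 64 with the DMSO and ipatasertib libraries exchanged), too few groupings for a share under 0.05, and a shared response remains an untested hypothesis.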
